A study of Mus musculus with 4 samples.

How the data were processed

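RNA was sequenced from 4 libraries, 2 of ILC2s sorted from small intestinal lamina propria and 2 of ILC2s sorted from mesenteric white adipose tissue of wild-type C57BL/6 mice aged 9 weeks, with libraries made from total RNA with a KAPA kit, per the labels. The sort markers are not given in the sources used here. The authors deposited RPKM values for 22083 genes in a single table, with a column per library and replicates not pooled. STAR 2.6.0, featureCounts 1.6.0 of the Subread package and the mouse build GRCm38 (mm10) were used, per the submitters' processing notes. The annotation, strand setting, treatment of multi-mapped reads and filters are not given in the sources used here. Groups and replicate numbers were taken from the sample titles, and every column matched a single title.

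RPKM is scaled to gene length and library size only, so a few abundant transcripts can lower all others. Column sums ranged from 136705 to 158718, and a repeat-derived gene, Gm10800, took 1.68% to 5.78% of them. RPKM values are not counts, so no count test was used. In single-exon genes with few reads, values multiplied by annotated length fell on whole reads within 0.1 for 86.2% to 88.1% of values at the depth that fitted best, against 20% by chance. This put the depth at 55800000 to 76000000 reads. Even numbers made up 65.6% to 72.5% of the whole values. In 6699 genes with at least 200 reads, the variance between libraries of a tissue was compared with the sampling noise of reads counted in pairs. It was 17.4 times (SI-ILC2s) and 21.4 times (WAT-ILC2s) this noise, so none was treated as a copy of another. This noise covers counting error only. An excess of even numbers is what counting both reads of a pair would give, but how reads were counted was not tested. Separate preparations of the same RNA could also exceed this noise. In all 4 libraries, 232 genes were listed at 0, and 13 of these were the mRNAs of the mitochondrial genome.

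Genes with an RPKM of at least 1 in at least 2 libraries were tested, which left 8230. Values were transformed to log2(RPKM + 1) and compared with limma 3.58.1 in R 4.3.3 (SI-ILC2 minus WAT-ILC2, variance trend, no robust option, all 4 libraries, no covariate). Benjamini-Hochberg adjustment ran over all tested genes, with a threshold of 0.05, and again over each list alone. The prior added 4.4 degrees of freedom to 2, for a total of 6.4. With 2 libraries against 2, an exact permutation test of a single gene cannot pass the threshold. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

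Before the data were examined, 32 gene lists were fixed: 18 of cell functions, 13 of markers of other cells and 1 of mitochondrial mRNAs. The functional lists were ILC2 identity, cytokines, chemokines, cytokine receptors, neuropeptide, lipid and nuclear receptors, homing and adhesion, costimulation and inhibition, immediate early genes, the NF-kappaB pathway, heat shock, the circadian clock, proliferation, fatty acids, cholesterol, glycolysis, amino acids and polyamines, interferon response and JAK-STAT signalling. The other-cell lists were adipocyte, fibroblast, endothelial, mesothelial, intestinal epithelium, B and plasma cell, T cell, macrophage and dendritic cell, MHC class II, granulocyte and mast cell, NK cell and ILC1, ILC3, and red cell. Older symbols were used for 6 list members, and 11 members, among them immunoglobulin and T cell receptor constant genes, were not used here. Lists with at least 4 tested genes (26) were compared with all other genes with camera at a preset correlation of 0.01. With an estimated correlation, camera instead takes its p-values from the 2 residual degrees of freedom of this fit. That setting has little power, so a call lost under it shows little. Fry tested whether the genes of a list moved, on balance, in 1 direction, without comparing them with other genes. Named genes were the 12 with the largest change in each direction among called genes with separated libraries and a mean of at least 5 RPKM, leaving out predicted genes and antigen receptor segments, up to 4 called members per direction of each list, the 2 most abundant members of each other-cell list, and a preset group of cytokine, receptor and lineage genes. The text gives examples of these, and some genes are not reported here. Coordinates and overlaps came from GENCODE M21 (GRCm38), in which 21016 symbols matched a single gene.

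The steps were tested on simulated data for this comparison, in which 200 genes were changed and 7996 genes passed the filter. With a 2-fold change 82.8% of the 99 such genes tested were recovered, with a 4-fold change 100% of 100, and 16 of 7797 unchanged genes were called. Recovered changes were understated, with medians of 0.79 and 1.56 on the log2 scale. The simulated reads were drawn independently, with the same variance for all genes and no effect shared by libraries of the same replicate number. The real libraries differ in these points and in the number of genes called, so the rates may not hold for them. The alternatives were pseudocounts of 0.1 and 0.5, no filter, a filter at 5 RPKM, rescaling to equal sums, median-of-ratios scaling, quantile normalization, no variance trend, robust variance, a test for more than 2-fold change, the replicate number as a block, leaving out each library, and for lists an estimated correlation and fry. Weighting by approximate reads with limma voom was added after the data had been seen.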

Results

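Group 2 innate lymphoid cells (ILC2s) are tissue-resident lymphocytes without antigen receptors that produce type 2 cytokines. RNA was sequenced from ILC2s that had been sorted from the lamina propria of the small intestine (SI-ILC2s) and from mesenteric white adipose tissue (WAT-ILC2s) of wild-type C57BL/6 mice aged 9 weeks. Each tissue was represented by 2 libraries, and 22083 genes had a value in each library. The values were RPKM, read counts scaled to gene length and sequencing depth, as the authors deposited them. The size of the value steps in single-exon genes put the depth at about 76000000 and 59500000 reads for the SI-ILC2 libraries and at 55800000 and 65500000 reads for the WAT-ILC2 libraries. The labels do not say whether the libraries of a tissue came from separate mice, so p-values measure only the spread between these libraries, which may be technical. Values below are mean RPKM ± SD of 2 libraries, and changes are SI-ILC2 minus WAT-ILC2 on the log2(RPKM + 1) scale, which understates the change of genes with low values. Means in parentheses are given without SD. They are replaced by the values of replicates 1 and 2, joined by "and", where leaving out 1 of them would move the mean by more than 1.5 times.

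The comparison asked how ILC2s of the intestine and of the fat depot beside it differ. For all genes below, a difference made by the isolation from each tissue cannot be told apart in this design from a difference of the ILC2s. The genes with the largest differences toward the intestine included Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, at 125 ± 5.82 RPKM in SI-ILC2s and 2.73 ± 0.109 in WAT-ILC2s. The largest difference toward adipose tissue was that of Ccr2, a chemokine receptor, at 58.3 ± 1.56 RPKM in WAT-ILC2s and 0.829 ± 0.0251 in SI-ILC2s. Il17rb, a subunit of the receptor for the alarmin IL-25, was higher in SI-ILC2s, and Il1rl1, which encodes the receptor for the alarmin IL-33, was higher in WAT-ILC2s. Gata3, the transcription factor that defines the lineage, had 366 ± 16.01 RPKM in SI-ILC2s and 368 ± 41.4 in WAT-ILC2s.

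Of 8230 genes tested, 1470 were higher in SI-ILC2s and 2436 were higher in WAT-ILC2s (limma, Benjamini-Hochberg adjusted p below 0.05). Among these, 494 and 736 genes changed by more than 1 on the log2 scale, and 90 and 80 by more than 2. Both SI-ILC2 libraries lay above both WAT-ILC2 libraries for 2456 genes (29.8%), and the reverse held for 3774 genes (45.9%), where chance gives 16.7% each way. SI-ILC2s held 37.6% of the calls, against 51.8% (1956 and 1817 genes) after median-of-ratios scaling 48.4% (1772 and 1886 genes) after quantile normalization and 28% (1105 and 2842 genes) after rescaling to equal sums. The median log2 change of all tested genes was -0.15, and it was 0, -0.02 and -0.33 after these scalings. Without SI-ILC2 replicate 1 the number of genes higher in WAT-ILC2s fell to 1492, and 133 and 117 genes passed a test for a change of more than 2-fold.

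**Figure D1:**
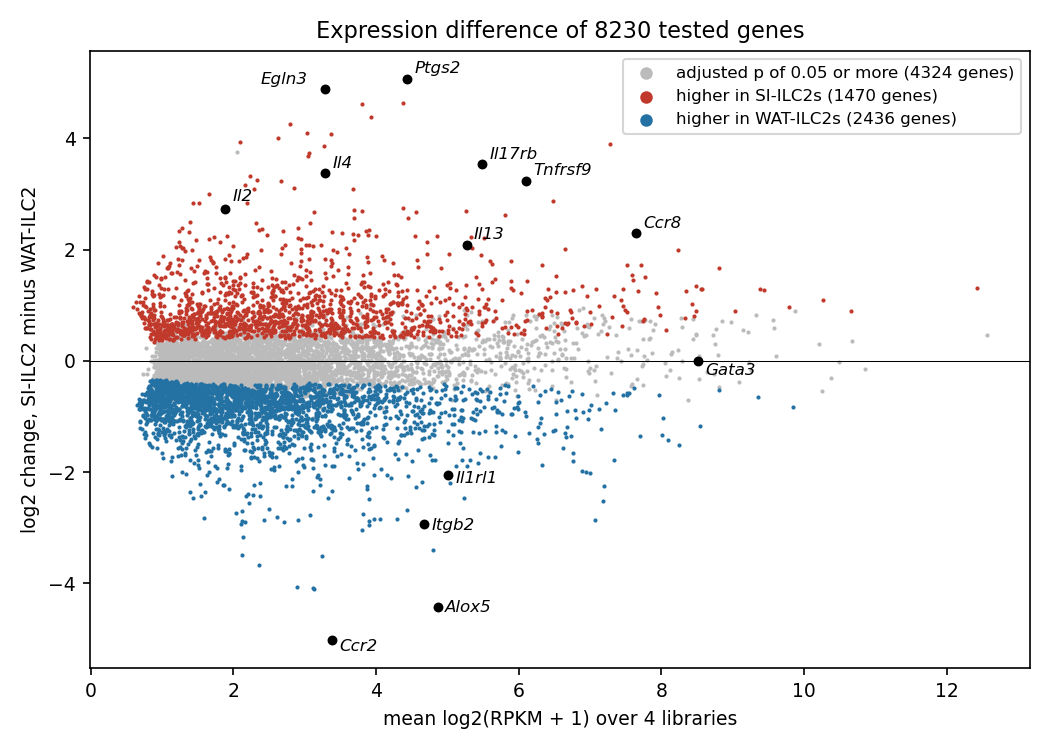
Change between tissues against expression level for the 8230 tested genes. The x axis is the mean log2(RPKM + 1) over the 4 libraries, the y axis is the change in log2(RPKM + 1) of SI-ILC2s minus WAT-ILC2s, and each point is a gene, coloured red for the 1470 higher in SI-ILC2s and blue for the 2436 higher in WAT-ILC2s, with black points for labelled genes such as Ptgs2 at 5.07 and Ccr2 at -5.02.

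The libraries of a tissue resembled each other more than those of different tissues. Across the tested genes, which are not independent replicates, Pearson's r of log2(RPKM + 1) was 0.985 within SI-ILC2s, 0.979 within WAT-ILC2s and 0.863 to 0.880 between tissues. The first principal component held 87.1% of the variance and separated the tissues.

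The 12 largest changes toward SI-ILC2s were led by Ptgs2 (chromosome 1, 150100031 to 150108227), which rose by 5.07 ± 0.13 (SE, adjusted p = 3.9e-05). Egln3 (chromosome 12, 54178981 to 54203860) and Epas1 (chromosome 17, 86753700 to 86833410), a prolyl hydroxylase and a transcription factor of the hypoxia pathway, were at 52.1 ± 8.22 and 68.6 ± 7.77 RPKM in SI-ILC2s and at 0.787 ± 0.00601 and 1.81 ± 0.0308 in WAT-ILC2s, changes of 4.88 and 4.63 with an adjusted p of 4.9e-05 for each. Abcb1a, which encodes a multidrug efflux pump and shares sequence with its paralog Abcb1b, was at 104 ± 25.5 against 3.25 ± 1.37 RPKM. The receptor tyrosine kinase gene Ret was at 32.7 ± 1.35 against 0.975 ± 0.112 RPKM, and the retinaldehyde reductase gene Dhrs3 at 35.8 ± 3.31 against 1.51 ± 0.0792. Gem, which encodes a small GTP-binding protein, was the most abundant of the 12 at 599 ± 3.56 against 39.5 ± 3.59 RPKM. Gzma, the gene of granzyme A, was at 15.9 ± 4.19 against 0.0827 ± 0.03 RPKM, and its WAT-ILC2 values rest on few reads. The remaining genes were Dkk3 (29.4 against 0.591 RPKM), Gjb2 (23.7 against 0.534 RPKM), Abhd17c (69.05 against 2.37 RPKM) and Basp1 (28.3 and 59.7 against 1.51 RPKM). Adjusted p-values of the 12 ranged from 3.9e-05 to 4.8e-04. Exons of Abcb1a overlap a gene on the opposite strand, and whether the authors' counting used strand is not given in the sources used here.

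Toward WAT-ILC2s, Ccr2 (chromosome 9, 124101950 to 124113557) fell by 5.02 from adipose tissue to intestine (SE 0.13, adjusted p = 3.9e-05). Alox5 (chromosome 6, 116410077 to 116461178), the 5-lipoxygenase of leukotriene synthesis, was at 135 ± 11.3 RPKM in WAT-ILC2s and 5.33 ± 0.392 in SI-ILC2s, a change of -4.42 with an adjusted p of 4.9e-05. Genes of calcium-binding proteins were also among the 12, namely S100a4 at 38.5 ± 21.4 against 1.14 ± 0.419 RPKM, S100a6 at 12.7 ± 4.65 against 0.469 ± 0.0943, and Anxa1, which encodes annexin A1, at 35.02 ± 6.77 against 1.11 ± 0.00714. Lgals1, the gene of galectin-1, was at 14.2 ± 5.88 against 0.306 ± 0.247 RPKM. Sema4a, a semaphorin gene, was at 29.5 ± 4.19 against 0.834 ± 0.403 RPKM, and Lpcat2, which encodes an enzyme of phospholipid remodelling, at 89.7 ± 8.05 against 7.58 ± 0.471. The others were Arl5b (39.4 against 3.87 RPKM), N4bp2l1 (40.8 against 4.37 RPKM), Myadm (31.03 against 1.83 RPKM) and the kinase gene Mapk12 (17.4 against 0.44 RPKM). Adjusted p-values of the 12 ranged from 3.9e-05 to 6.5e-04. S100a4, Sema4a, Myadm and N4bp2l1 share exons with a gene on the same strand. Red cell transcripts and some of those of fibroblasts and endothelium, given with the markers of other cells, were also higher in WAT-ILC2s, and the endothelial gene Pecam1 was lower.

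Among 22 tested genes of the ILC2 identity list, 8 were higher in SI-ILC2s, 5 were higher in WAT-ILC2s and 9 did not pass the test. Il17rb (chromosome 14, 29996135 to 30008896) was at 152 ± 16.7 RPKM in SI-ILC2s and 12.3 ± 2.83 in WAT-ILC2s (log2 change 3.54, SE 0.19, adjusted p = 2.0e-04), and its exons overlap Actr8 on the opposite strand. Il1rl1 (chromosome 1, 40429570 to 40465415) was at 64.5 ± 1.61 RPKM in WAT-ILC2s and 14.8 ± 0.751 in SI-ILC2s (log2 change -2.05, SE 0.14, adjusted p = 2.8e-04). Also higher in SI-ILC2s were the transcription factor genes Tcf7 (11.4 against 2.27 RPKM), Rxrg (7.66 against 1.37 RPKM) and Rora (93.98 against 49.9 RPKM), the costimulatory receptor gene Icos (62.6 against 15.9 RPKM) and the receptor kinase gene Kit (32.7 against 20.98 RPKM). Higher in WAT-ILC2s were the surface protein genes Thy1 (22.9 against 2.49 and 5.08 RPKM) and Ly6a (33.3 against 11.2 RPKM), Arg1 (170.1 against 56.3 RPKM), which encodes arginase-1, and Il7r (65.4 against 36.1 RPKM). Gata3, Il2ra (25.1 against 23.9 RPKM) and Klrg1 (119 against 154 RPKM) had adjusted p-values of 0.99, 0.7 and 0.19. Ptprc, the pan-leukocyte marker CD45, was at 19.1 ± 2.28 RPKM in SI-ILC2s and 27.6 ± 3.51 in WAT-ILC2s (adjusted p = 0.041).

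Of 26 tested cytokine and growth factor genes, 11 were higher in SI-ILC2s and 7 in WAT-ILC2s. Il4, Il13 and Il2 were higher in SI-ILC2s, at 31.1 ± 9.47, 81.98 ± 32.5 and 8.61 ± 1.63 RPKM against 2.04 ± 0.301, 18.4 ± 7.02 and 0.45 ± 0.298, with log2 changes of 3.37, 2.09 and 2.73 and adjusted p-values of 2.8e-04, 0.0041 and 3.9e-04. Il3 was also higher, at 4.79 ± 0.274 against 0.168 ± 0.0356 RPKM, as was Il17a, at 4.57 ± 1.04 RPKM in SI-ILC2s and at 0 and 0.117 RPKM in the WAT-ILC2 libraries, which for both genes rest on few reads. Tgfb1, Vegfa and Tnf were higher in WAT-ILC2s, at 66.99 ± 13.8, 14.1 ± 2.23 and 21.2 ± 2.43 RPKM against 17.99 ± 8.03, 3.16 ± 1.005 and 5.83 ± 0.627, as was the bone morphogenetic protein gene Bmp7 (17.02 against 5.90 RPKM). Il5 was at 140.0 ± 8.58 RPKM in SI-ILC2s and 102 ± 6.64 in WAT-ILC2s, and its adjusted p of 0.051 missed the threshold, which it passed with median-of-ratios scaling (adjusted p = 0.019). Csf2 and Areg, the genes of GM-CSF and amphiregulin, were at 179.8 and 210.3 RPKM in SI-ILC2s and 224 and 220.1 in WAT-ILC2s, with adjusted p-values of 0.16 and 0.85. Il9 stayed below the filter at 0.53 and 0.29 RPKM. Of 6 tested chemokine genes, 2 were higher in SI-ILC2s, namely Cxcl3 (36.3 against 3.38 RPKM) and Cxcl16 (1.45 against 0.685 RPKM). Exons of Il5, Csf2 and Cxcl16 overlap genes on the opposite strand.

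**Figure D2:**
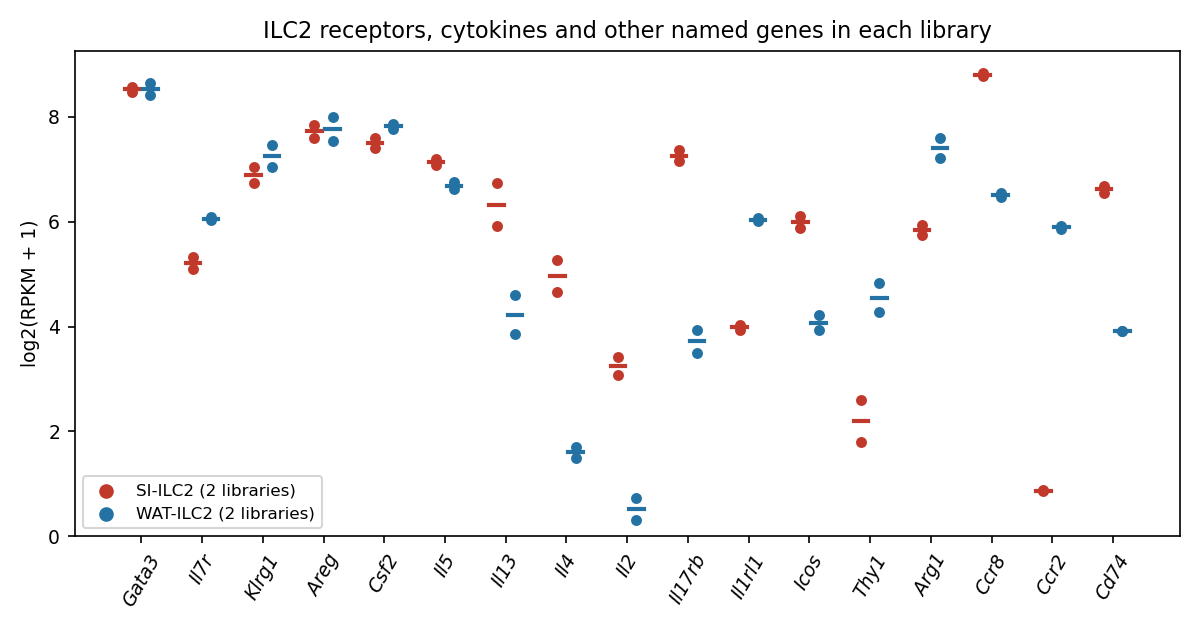
Expression of 17 named genes in each library. The y axis is log2(RPKM + 1), each point is a library (red, 2 SI-ILC2 libraries and blue, 2 WAT-ILC2 libraries), and short bars are means, with Il17rb and Ccr8 higher in SI-ILC2s, Ccr2 and Il1rl1 higher in WAT-ILC2s, and Gata3 near 366 RPKM in SI-ILC2s and 368 in WAT-ILC2s.

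Receptors of cytokines changed in both directions, with 7 of 27 tested genes higher in SI-ILC2s and 12 in WAT-ILC2s. Besides Il17rb, the SI-ILC2 side held Tnfrsf1b, a receptor for tumour necrosis factor, at 32.8 ± 0.598 against 5.62 ± 0.0111 RPKM, Il15ra (13.6 against 5.19 RPKM) and Il21r (1.99 against 0.327 RPKM). The WAT-ILC2 side held Il10ra, a subunit of the receptor for interleukin-10, at 51.1 ± 5.89 against 9.74 ± 0.0446 RPKM, Il1rap (2.85 against 0.599 RPKM), the partner of Il1rl1, and Il6st (2.36 against 0.585 RPKM). Among receptors for neuropeptides, lipids and nuclear ligands, 7 of 20 were higher in SI-ILC2s and 7 in WAT-ILC2s. These counts were 10 and 6 with median-of-ratios scaling and 4 and 7 after rescaling to equal sums. Ahr, the aryl hydrocarbon receptor gene, was at 10.8 ± 1.24 against 1.11 ± 0.0982 RPKM, higher in SI-ILC2s, as was Ptger4 (15.1 against 7.75 RPKM). Ltb4r1, a leukotriene B4 receptor gene, was at 42.6 ± 16.01 against 4.93 ± 1.52 RPKM and Ptgir, the prostacyclin receptor gene, at 53.5 ± 3.60 against 7.57 ± 1.35, both higher in WAT-ILC2s, as were Ramp1 (3.92 against 0.414 RPKM) and Rara (9.90 against 2.96 RPKM).

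Homing and adhesion genes included 7 of 21 higher in SI-ILC2s and 10 higher in WAT-ILC2s. The chemokine receptor gene Ccr8 was at 445 ± 13.04 RPKM in SI-ILC2s and 89.8 ± 3.99 in WAT-ILC2s (log2 change 2.30, adjusted p = 3.0e-04), and Ccr9, a gut-homing receptor gene, at 6.50 ± 1.06 and 2.18 ± 0.444. Cd69, an activation and residency marker, was at 155 ± 4.98 against 52.99 ± 2.40 RPKM, and Itga4 (4.98 against 2.37 RPKM) was also higher in SI-ILC2s. Besides Ccr2, WAT-ILC2s had higher Itgb2, the common subunit of the leukocyte integrins, at 69.9 ± 4.62 against 8.24 ± 0.449 RPKM, and higher Cxcr4 (53.02 against 18.3 RPKM). Of 25 costimulatory and inhibitory genes, 11 were higher in SI-ILC2s and 4 in WAT-ILC2s. The SI-ILC2 side was led by Tnfrsf9, which encodes 4-1BB, at 211 ± 30.7 against 21.5 ± 4.19 RPKM, with Nt5e (9.52 against 1.63 RPKM), Cd28 (4.36 against 0.469 and 0.223 RPKM) and Icos. The WAT-ILC2 side comprised Icosl, the gene of the ligand of ICOS, at 20.9 ± 0.234 against 2.23 ± 0.379 RPKM, Cd226 (10.4 against 1.93 RPKM), Tnfsf9 (6.82 against 1.54 RPKM), the ligand gene of Tnfrsf9, and Cd274 (20.4 against 8.03 RPKM), which encodes PD-L1.

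Immediate early genes, induced within minutes of stimulation, were higher in SI-ILC2s for 6 of 26 and higher in WAT-ILC2s for 13. Klf2, Jun, Myc and Nr4a2 were higher in SI-ILC2s, with Klf2 (24.97 against 7.75 RPKM) and Myc (36.2 against 14.3 RPKM) as examples, and Ier3 (17.6 against 3.44 RPKM), Btg2 (192 against 60.2 RPKM), Jund (172 against 68.1 RPKM) and Nr4a3 (128 against 50.7 RPKM) were higher in WAT-ILC2s. Of 21 genes of the NF-kappaB pathway, 3 were higher in SI-ILC2s, namely Nfkbiz (128 against 80.3 RPKM), Relb (32.7 against 21.3 RPKM) and Rel (24.7 against 17.3 RPKM). Another 9 were higher in WAT-ILC2s, led by the inhibitor genes Nfkbid (349 against 59.6 RPKM) and Nfkbie (90.7 against 30.8 RPKM), Icam1 (43.8 against 5.62 and 16.1 RPKM) and Gadd45b (516 against 179 RPKM). After rescaling to equal sums the counts were 0 and 11, so the calls of Nfkbiz, Relb and Rel were lost. Genes of JAK-STAT signalling included 4 of 19 higher in SI-ILC2s and 7 in WAT-ILC2s, or 4 and 4 with median-of-ratios scaling, with Stat3 (85.9 against 22.1 RPKM) on the SI-ILC2 side and Pim3 (78.8 against 32.02 RPKM), Bcl2 (7.97 against 2.33 RPKM) and Socs2 (46.95 against 23.3 RPKM) on the WAT-ILC2 side. Stat3 and Stat5a overlap on opposite strands. Among interferon response genes, 6 of 16 were higher in SI-ILC2s, such as Gbp3 (16.8 against 6.46 RPKM) and Ifit1 (3.54 against 0.434 and 0.986 RPKM), and 4 were higher in WAT-ILC2s, such as Irf7 (13.3 against 8.36 RPKM) and Usp18 (2.44 against 0.727 RPKM).

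Heat shock genes rose in SI-ILC2s for 5 of 15 and fell for 1, and the list passed the set test (camera, adjusted p = 0.036, and adjusted p = 0.53 with an estimated correlation). Its estimated correlation was 0.01, the same as the preset value, and its unadjusted camera p still went from 0.0042 to 0.11. A higher correlation thus does not account for the larger p-value of this list, which goes with the 2 residual degrees of freedom used in that setting. Hspa5, the chaperone of the endoplasmic reticulum, was at 1241 ± 82.95 RPKM in SI-ILC2s and 636 ± 34.8 in WAT-ILC2s, and Hsp90aa1 at 252 ± 6.25 and 118 ± 17.2. Hspa1a and Hspa1b, near-identical copies whose reads cannot be assigned with certainty, were at 53.3 and 70.03 against 15.99 and 26.2 RPKM, and Hspb1 (2.49 against 1.20 RPKM) was the member that fell. The list's call was lost without SI-ILC2 replicate 1, with quantile normalization and with the estimated correlation. Circadian clock genes were higher in SI-ILC2s for 6 of 13, including Hlf (26.5 against 6.98 RPKM), Bhlhe40 (328 against 112 RPKM) and Nfil3 (113 against 41.2 RPKM), and higher in WAT-ILC2s for 3, namely Tef (1.93 against 0.941 RPKM), Dbp (3.57 against 2.23 RPKM) and Clock (1.28 against 0.707 RPKM), with an adjusted p of 0.059 for the list.

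Metabolic lists held calls in both directions. Tph1, which encodes the rate-limiting enzyme of serotonin synthesis outside the brain, was at 14.6 ± 1.97 RPKM in SI-ILC2s and 0.638 ± 0.188 in WAT-ILC2s, and Odc1, the rate-limiting enzyme of polyamine synthesis, at 801 ± 84.8 and 252 ± 36.8. They belonged to the amino acid and polyamine list, where 5 of 22 genes were higher in SI-ILC2s and 8 in WAT-ILC2s, the latter including Arg1, Ass1 (10.1 against 0.818 and 2.20 RPKM), Slc7a8 (47.8 against 14.04 RPKM) and Slc38a2 (124 against 46.5 RPKM). Fatty acid genes were higher in SI-ILC2s for 4 of 27, such as Plin2 (35.1 against 19.6 RPKM) and Acsl4 (23.9 against 11.97 RPKM), and higher in WAT-ILC2s for 12, such as the fatty acid translocase gene Cd36 (13.5 against 0.991 RPKM), Mgll (2.02 against 0.227 RPKM) and Pnpla2 (34.3 against 15.1 RPKM). Of 19 glycolysis genes, 3 were higher in SI-ILC2s, namely Hif1a (26.4 against 10.8 RPKM), Pgam1 (28.3 against 16.6 RPKM) and Hk2 (11.3 against 7.48 RPKM), and 10 in WAT-ILC2s, including the glucose transporter gene Slc2a3 (14.1 against 2.76 RPKM) and Eno1 (141 against 58.5 RPKM). The glycolysis counts were 6 and 7 with median-of-ratios scaling and 2 and 10 after rescaling to equal sums. Cholesterol synthesis genes were higher in SI-ILC2s for 2 of 18, namely Msmo1 (4.998 against 2.21 RPKM) and Cyp51 (107 against 58.96 RPKM), and higher in WAT-ILC2s for 5, such as Hmgcs1 (8.29 against 4.61 RPKM). Of 12 tested proliferation genes, 7 were higher in WAT-ILC2s, including Hmgb2 (58.9 against 29.7 RPKM), Mcm6 (10.3 against 4.77 RPKM) and Tk1 (2.14 against 0.596 RPKM), with an adjusted p of 0.059 for the list (0.043 with median-of-ratios scaling, and 0.53 with an estimated correlation), and 18 further members stayed below the filter.

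Markers of other cell types were compared because sorted cells can carry RNA of their neighbours. All 6 tested MHC class II genes were higher in SI-ILC2s, and the list passed the set test (camera, adjusted p = 1.6e-04). With an estimated correlation, which was 0.57, and only 2 degrees of freedom, the adjusted camera p of the list was 0.53. Another 4 members stayed below the filter, among them Ciita at 0.054 RPKM in SI-ILC2s and 0.067 in WAT-ILC2s. H2-Aa and H2-Eb1 passed the filter through the SI-ILC2 libraries alone. Cd74, the invariant chain, was at 96.9 ± 6.56 against 14.1 ± 0.0779 RPKM, H2-Eb1 at 11.3 ± 1.63 against 0.708 ± 0.0743 and H2-Oa at 60.4 ± 0.767 against 22.97 ± 3.17, and these genes have related copies. The 4 tested genes of the NK cell and ILC1 list were higher in SI-ILC2s (adjusted p = 5.5e-04, and adjusted p = 0.53 with an estimated correlation), namely Gzma, Gzmb (6.68 against 0.0127 and 0.14 RPKM), Nkg7 (12.1 against 3.36 and 1.32 RPKM) and Cd160 (2.91 against 0.0534 RPKM). The other 14 members of that list stayed below the filter. Gzma, Gzmb and Cd160 passed it through the SI-ILC2 libraries alone. The filter thus favoured this direction, and the set test adds little to these values. With no filter the list was also called. Of the B and plasma cell list, Igj (6.26 RPKM in SI-ILC2s, 0.0129 and 0 in the WAT-ILC2 libraries), Cd79b (15.2 against 2.47 RPKM) and Xbp1 (46.9 against 21.02 RPKM) were higher in SI-ILC2s and 11 members stayed below the filter. Of 6 tested ILC3 genes, 3 were higher in SI-ILC2s, namely Il17a, Il22 (2.63 against 0.0649 and 0.0137 RPKM) and Il17f (1.33 against 0.17 and 0.0772 RPKM), and Nrp1 (2.13 against 0.187 and 0.389 RPKM) was higher in WAT-ILC2s. In the same list Gpx1 was at 10.7 and 12.7 RPKM and Ltb at 2.85 ± 1.44 and 6.99 ± 4.19, without a call.

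Markers of red cells, fibroblasts and endothelium were higher in WAT-ILC2s where they were called, with Pecam1 as the exception. Most members of the fibroblast (12), endothelial (8) and adipocyte (14) lists stayed below the filter. Dcn, Col3a1, Lyz2, Fabp4 and Cpa3 passed it through the WAT-ILC2 libraries alone, which favoured a call in this direction. All 5 tested red cell genes were higher, with Hba-a1 at 33.02 ± 11.2 RPKM in WAT-ILC2s and 8.57 ± 5.997 in SI-ILC2s and Hbb-bt at 18.9 ± 6.32 and 3.88 ± 2.89, and near-identical copies make the values of single globin genes uncertain. Of 6 tested fibroblast genes, 3 were higher, namely Dcn (6.11 and 1.86 against 0.0784 RPKM), Sparc (6.25 against 1.42 and 0.648 RPKM) and Col3a1 (2.33 and 1.09 against 0.0639 RPKM), and Acta2 (3.13 against 0.096 and 3.68 RPKM) was not called. Of 4 tested endothelial genes, Plvap (5.17 and 16.2 against 2.23 RPKM) and Esam (3.31 against 0.608 and 1.94 RPKM) were higher in WAT-ILC2s and Pecam1 (4.18 against 2.50 RPKM) in SI-ILC2s. Of 5 tested macrophage and dendritic cell genes, Lyz2 (4.51 against 0.482 RPKM), Zbtb46 (2.66 against 1.11 RPKM) and Xcr1 (8.66 against 4.79 RPKM) were higher. The other 15 members stayed below the filter, among them Itgax, Flt3 and Clec9a at 0.079, 0.0705 and 0.02 RPKM in WAT-ILC2s. Among 8 tested T cell genes, 5 were higher in WAT-ILC2s, including Lat (49.5 against 26.2 RPKM), Cd3g (15.99 against 6.01 RPKM) and Lck (7.06 against 3.71 RPKM), and Cd6 (1.33 against 0.581 RPKM) was higher in SI-ILC2s. Another 6 members stayed below the filter, among them Cd3d, Cd5, Cd8a and Cd8b1 at 0.053, 0.032, 0.034 and 0.023 RPKM in WAT-ILC2s. Bcl11b of this list also belonged to the ILC2 identity list. The single tested adipocyte gene Fabp4 (3.87 against 0.214 RPKM), the mast cell genes Hdc (14.7 against 3.64 RPKM) and Cpa3 (1.18 against 0.191 RPKM), and Epcam (8.07 against 5.36 RPKM) and Lgals4 (4.31 against 1.23 RPKM) of the intestinal epithelium list were higher in WAT-ILC2s. The adipocyte gene Acsl1 was at 0.662 and 0.649 RPKM, and no mesothelial gene passed the filter, with Krt19 and Upk3b at 0.324 ± 0.125 and 0.0658 ± 0.00212 RPKM in SI-ILC2s and 0.942 ± 0.934 and 0.31 ± 0.181 in WAT-ILC2s. The 13 mRNAs of the mitochondrial genome were listed at 0 in all 4 libraries and say nothing about RNA quality.

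**Figure D3:**
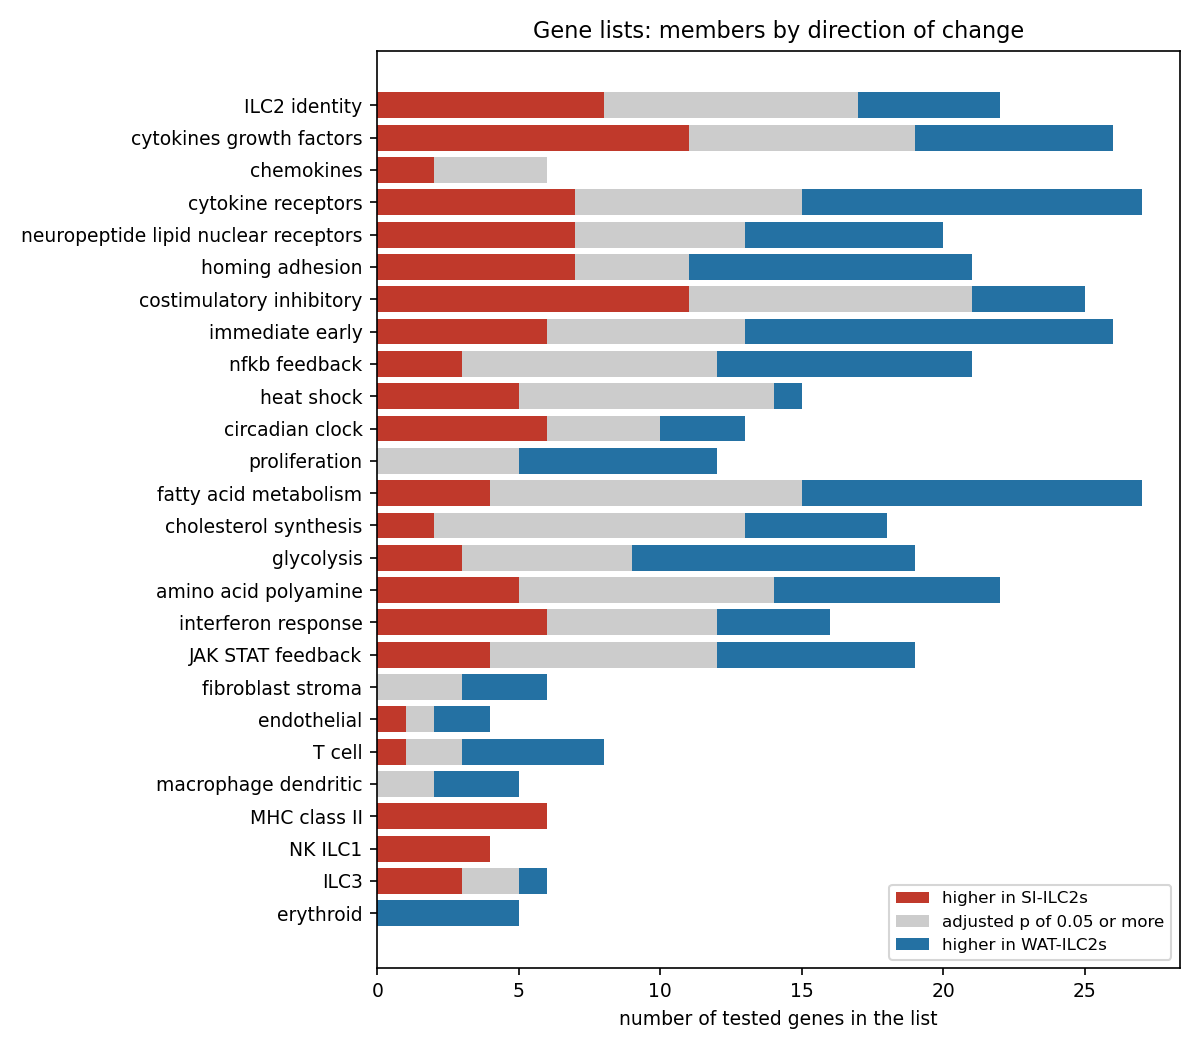
Members of the 26 gene lists tested, by direction of change. Bars count tested genes per list, with red for genes higher in SI-ILC2s, grey for genes with an adjusted p of 0.05 or more and blue for genes higher in WAT-ILC2s, and all 6 MHC class II genes and all 5 red cell genes fall on opposite sides.

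Counts adjusted over the list alone were larger in 8 of the lists, reaching 12 and 7 for cytokines, 8 and 7 for neuropeptide, lipid and nuclear receptors, 12 and 4 for costimulatory genes, 3 and 11 for the NF-kappaB pathway, 7 and 3 for clock genes, 0 and 8 for proliferation, 5 and 10 for glycolysis and 5 and 9 for the amino acid list (SI-ILC2s and WAT-ILC2s). Camera called 3 of 26 lists. With an estimated correlation and 2 residual degrees of freedom it called 0, and the lowest unadjusted p was 0.079. That setting has little power to call any list. Fry, which does not compare a list with other genes, called 18. Leaving out a library changed the number of lists called to between 5 and 9. With median-of-ratios scaling the counts were 8 and 1 for heat shock, 7 and 1 for clock genes (also with quantile normalization) and 6 and 2 for the interferon response. After rescaling to equal sums they were 4 and 3 for clock genes, 6 and 6 for the interferon response and 11 and 6 for costimulatory genes. Calls were also lost for Hk2, Pecam1 and Ptger4 after rescaling to equal sums, for Clock, Dbp, Epcam, Irf7 and Ptprc with median-of-ratios scaling, and for Clock, Dbp, Epcam, Hspb1, Nfkbiz and Relb with quantile normalization. Exons of Acsl1, Ahr, Bcl2, Bhlhe40, Ccr9, Cd160, Cd274, Cyp51, Dbp, Gata3, H2-Oa, Hif1a, Hmgcs1, Hspa1a, Icam1, Il1rap, Irf7, Itga4, Jun, Jund, Lpcat2, Mgll, Ptger4, Rora, Tef, Tk1, Tnfsf9 and Usp18 also overlap a gene on the opposite strand, and those of Ccr9, Cd74, Col3a1, Gata3, Hif1a, Lat, Lck and Nrp1 overlap a gene on the same strand, so their values may hold reads of other genes.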

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

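The voom weighting was chosen after the data had been seen and the other alternatives before. Of 195 named genes with a test, 186 were called, and no called gene changed direction under those of the 16 alternatives that tested it, which for the filter at 5 RPKM were 149 of the 195 genes and for voom 194. The called genes were chosen on these same libraries, so little change of direction could arise, and this says nothing about other libraries. Uncalled genes changed sign when a library was left out, with log2 changes of -1.91 to 0.184 for Acta2, -0.285 to 0.178 for Areg, -0.118 to 0.111 for Gata3 and -0.545 to 0.185 for Gpx1. Areg (0.137) and Gata3 (0.187) also did so with median-of-ratios scaling and Il2ra (-0.0857) with rescaling to equal sums, and the cause was not tested. Calls were lost for 122 genes in the test for more than 2-fold change, which asks for a larger effect, for 13 with no filter, and for 4 to 25 when a library was left out. Genes higher in SI-ILC2s numbered 899 and genes higher in WAT-ILC2s 1182 with the filter at 5 RPKM, where 3933 genes were tested, and 133 and 117 in the test for more than 2-fold change. Leaving out a library gave 983 to 1595 and 1492 to 2551 genes, with the lone library of a tissue assumed to vary like the others, and the total degrees of freedom were then 429.1 and 195.6 without WAT-ILC2 replicates 1 and 2, against 6.4. Voom weighting gave 1343 and 2442. Lists called numbered 13 with no filter, where 31 were tested, 7 rescaled to equal sums (with clock, costimulatory, cytokine and proliferation genes added), 5 with median-of-ratios scaling (proliferation and red cell genes added), 5 to 9 without a library, 0 with an estimated correlation and 18 with fry, and apart from the filter the cause was not tested. With the filter at 5 RPKM, 3 of 21 lists were called, among them clock genes. The NK cell and ILC1 list then had too few genes to be tested. The lowest correlation within a tissue, 0.979, became 0.971 with the filter at 5 RPKM, which leaves fewer genes.

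The labels give both tissues the numbers 1 and 2 without saying that they pair. With the number as a replicate block, 2271 genes were higher in SI-ILC2s and 3430 in WAT-ILC2s, and 7 lists were called, with clock, red cell, fibroblast and proliferation genes added to the 3. Among the 195 named genes, 5 that had not been called were called with the block, and 0 calls were lost. The differences between replicates 2 and 1 in the 2 tissues correlated across genes with r = 0.57, and the second principal component (10.2% of variance) separated the numbers. The correlation was 0.53 after adjustment for length, GC content and level in 7930 genes, and 0.56 without markers of other cells and ribosomal protein genes.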

Other observations

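The 7 added lists and the tests of explanations in this part were chosen after the values had been seen, while the 18 fibroblast markers and the MHC class II and NK cell and ILC1 lists had been fixed before. Apart from the ribosomal protein genes, taken by symbol, the added lists were drawn up around genes seen to differ, so their counts describe these genes and no set test of them is given. In a list of S100, annexin, galectin, cytoskeletal and some membrane protein genes, 23 of 26 tested were higher in WAT-ILC2s. Vim, the gene of the intermediate filament vimentin, was at 364 ± 48.8 RPKM in WAT-ILC2s and 48.8 ± 3.41 in SI-ILC2s, and Ahnak, which encodes a large scaffold protein, at 4.53 ± 0.68 and 1.59 ± 0.258. Eicosanoid genes were higher in WAT-ILC2s for 10 of 18 and in SI-ILC2s for 3, with Alox5 and Ptgs2 at opposite ends.

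Ribosome biogenesis genes were higher in SI-ILC2s for 20 of 34 and in WAT-ILC2s for 3. Ribosomal protein genes were higher in SI-ILC2s for 20 of 78, or 2 when adjusted over the list alone (camera, adjusted p = 4.3e-11 over 7 added lists, and adjusted p = 0.46 with an estimated correlation). From replicate to replicate they differed by -0.38 in SI-ILC2s and -0.78 in WAT-ILC2s on the log2 scale (number 2 minus number 1). This shift had the same sign in both tissues, and the fit without a block counts it as spread. The labels do not say whether the numbers mark a shared batch. NRF2 target genes were higher in SI-ILC2s for 4 of 17 and in WAT-ILC2s for 1, hypoxia genes for 4 and 8 of 17, and retinoid genes for 4 and 2 of 9.

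MHC class II genes and Cd79b were higher in SI-ILC2s, with Cd74 at 96.9 RPKM. B cells in the sorts would bring Cd79a and Ms4a1, and the higher of their SI-ILC2 means was 0.177 RPKM, far below Cd79b at 15.2. Igj and Xbp1 of the same list were also higher in SI-ILC2s, Igj at 6.26 RPKM, with the plasma cell genes Mzb1 and Derl3 at 0.127 ± 0.128 and 0.2 ± 0.0517, and plasma cells remain open for Igj. Macrophages would bring C1qa, C1qb, C1qc and Lyz2, and the highest of their means was 0.482 RPKM, with Lyz2 higher in WAT-ILC2s. Dendritic cells cannot be told apart from a difference of the ILC2s themselves, an untested hypothesis, since 0 of Itgax, Flt3, Clec9a and Zbtb46 were higher in both SI-ILC2 libraries at 1 RPKM or more, and Zbtb46 and Xcr1 were higher in WAT-ILC2s, but a small share of these cells could bring much Cd74 and little of these genes.

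Granzyme genes, Nkg7 and Cd160, and Il17a, Il17f and Il22, were higher in SI-ILC2s, with Gzma at 15.9 RPKM. NK cells, ILC1s or CD8 T cells would bring Prf1, Ccl5 and 9 further markers (Ncr1, Klrb1c, Eomes, Klrd1, Tbx21, Cd8a, Cd8b1, Cd3d and Cd5), and the highest SI-ILC2 mean of the 11 was 0.966 RPKM, for Prf1. Ccl5 was at 0.572 ± 0.272 RPKM. Such cells cannot be told apart from a difference of the ILC2s for the granzyme transcripts, since the levels are low but 6 of the 11 markers, Prf1 among them, were higher in both SI-ILC2 libraries. These values do not bear on ILC3s, which remain open for the interleukin transcripts. A difference between ILC2s of the tissues also remains open and was not tested.

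Ccr2, Alox5, Vim and S100 genes were higher in WAT-ILC2s. Monocytes or macrophages in the sorts would bring more Lyz2 than Ccr2 or Alox5, and Lyz2 gained 4.03 RPKM in WAT-ILC2s, 7.0% of the 57.4 RPKM gained by Ccr2, the lesser gain of the pair. Fibroblasts would bring their collagens and proteoglycans, and the 18 fibroblast markers together gained 14.6 RPKM, 4.6% of the 315.4 RPKM gained by Vim. These values argue against monocytes or macrophages as the source of most of the Ccr2 and Alox5 difference and against fibroblasts for most of that of Vim. Endothelial cells were not tested as a source of Vim, and of their markers Plvap and Esam were higher in WAT-ILC2s and Pecam1 lower. A difference between ILC2s of the tissues, or one made by the isolation from each tissue, stays open as a hypothesis. The fibroblast markers gained 29.5% as much as S100a4 and S100a6 together, and WAT-ILC2 replicates 1 and 2 had 6.11 and 1.86 RPKM of Dcn, 53.6 and 23.4 of S100a4 and 15.9 and 9.36 of S100a6, so stromal cells cannot be told apart from a difference of the ILC2s for these S100 genes.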
